A study of Gallus gallus with 4 samples.

How the data were processed

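The series holds 4 libraries from DT40 cells: a streptavidin pull-down and an input for tagged SMC2, and the same pair for tagged CAP-H. Per the labels' protocols, the cells were blocked in mitosis, crosslinked with 1% formaldehyde and sonicated, and single-end reads of 50 bp were sequenced. The submitters' processing notes name BWA and the genome build galGal4, with no versions. Each pull-down had a peak list and a profile around the TSS. No files of the input libraries were used here, and the read depth of the libraries is not given in the sources used here.

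Each peak list covers 1 library, since the deposited files are assigned to single samples; peaks bear the names that the caller MACS writes. Its version, control and threshold are not given in the sources used here. The SMC2 list has a score per peak, the authors' own value, from 50.02 to 3100; its form is that of a MACS score of minus 10 times the log10 of p, but no header says so. The score was used only to rank or filter SMC2 peaks. The CAP-H list has no score. The deposited TSS profiles give, per the file headers, a Sample, a Control and a Difference value at each of 10001 bases. Sample and Control are a signal per base, a whole number everywhere, in the authors' files; how it was aggregated over TSSs, and over how many, is not given in the sources used here. Difference equalled Sample minus Control at every base of both files. Every Control value was a multiple of 2 in the SMC2 file and of 3 in the CAP-H file, while Sample values were not, and neither the reason nor the library that Control holds is given in the headers.

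Peak coordinates are printed counted from 1 in galGal4. Peaks were compared by overlap of at least 1 bp. The share that overlapped was set beside 1000 shuffles of the other list within its chromosomes, drawn with a fixed seed, each peak keeping its width. Shares have exact Clopper-Pearson binomial intervals, counts exact Poisson intervals, and ratios of counts exact conditional intervals, all at 95% and for counting error only. Relative ratios of counts between chromosomes have log-normal intervals. The ratio of median scores has a percentile interval from 2000 bootstrap draws of peaks, which describes these peaks and not replicates. Chromosomes were classed as macrochromosomes (1 to 5), intermediate (6 to 10), microchromosomes (11 to 28), Z, W and unplaced sequence. Their lengths were taken as the highest coordinate in either list, as no genome of that build was used here. Profile flanks were the bases beyond 4000 bp on either side; the SD given with them is over bases, which are not independent. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The overlap step was tested on simulated data before use: with 0%, 30% and 60% of 4369 CAP-H peaks planted on SMC2 peaks beyond chance, it returned -0.282%, 28.6% and 58.5%. Both simulated lists were placed at random within chromosomes, and planted peaks were exact copies of SMC2 peaks. The simulation thus checks the computation, and not whether random placement is a fair model for clustered peaks.

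Groups, tests and alternatives were fixed before the data were examined, except where the text says otherwise. The rule for named regions was the 10 peaks with the highest score in each list, the 5 windows of 100 kb with most peaks in each list, and the genes of both subunits. Ties were named in full. The rule also covered genes with the highest TSS values and members of 20 fixed gene lists. Those parts were not run, since the profiles hold no value per gene and no annotation of galGal4 was used here. The gene table at hand is of another assembly, GRCg7b, and was used only for the chromosome of SMC2 (Z) and of NCAPH, which encodes CAP-H (22). Peaks on unplaced sequences were counted but not named. The alternatives tried were other rules of overlap, filters on score, placed chromosomes alone, merging of nearby peaks, 1-Mb windows and other profile flanks.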

Results

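Condensin, the ring-shaped complex that compacts chromosomes for cell division, was mapped in DT40 cells, a chicken B cell lymphoma line, held in mitosis with 500 ng/ml nocodazole. The tagged subunits were SMC2, an ATPase shared by condensin I and condensin II, and CAP-H, which belongs to condensin I alone. Each carried a streptavidin-binding tag and replaced the untagged protein, whose expression was shut off with 2 ng/ml doxycycline. DNA crosslinked to the tagged protein was pulled down on streptavidin and sequenced, an assay called ChAP-seq. The labels name 4 libraries: 1 pull-down and 1 input for each subunit. There were no replicates, so every interval given here covers counting error only and no difference has a replicate check. The read depth of the libraries is unknown, because the files hold peaks and profiles rather than reads. The comparisons address where condensin lies in the genome and how far its subunits coincide.

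The first comparison asked where in the genome the peaks of each subunit lie. Peaks were concentrated on the microchromosomes, the small, gene-dense and GC-rich chromosomes of birds. On chromosomes 11 to 28 the SMC2 list had 18.6 peaks per Mb (95% exact Poisson interval 17.9 to 19.2), against 2.59 (2.46 to 2.72) on macrochromosomes 1 to 5, a ratio of 7.18 (6.76 to 7.63). For CAP-H the densities were 11.3 (10.8 to 11.8) and 1.92 (1.81 to 2.03) peaks per Mb, a ratio of 5.87 (5.46 to 6.32). Chromosomes 6 to 10 lay between, at 4.19 SMC2 and 4.01 CAP-H peaks per Mb. The Z chromosome was below all of these classes, with 1.53 SMC2 peaks per Mb (1.27 to 1.82) and 1.14 CAP-H peaks per Mb (0.922 to 1.397). Densities were not corrected for the number of copies of each chromosome, including Z, in the cells, which was not measured here.

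Among large and small autosomes the SMC2 density was 1.58 peaks per Mb on chromosome 3, 57.8 on chromosome 28 and 60.1 on chromosome 27. Chromosome 16 was highest. This chromosome, which carries the nucleolar organiser and the major histocompatibility complex, had 78.6 SMC2 peaks per Mb (55.9 to 107) and 40.3 CAP-H peaks per Mb (24.6 to 62.2). Its peaks reached no further than position 496238, so both intervals are wide. On chromosomes 27 and 28 the CAP-H density was 30.3 and 31.0 peaks per Mb. In all, the SMC2 list held 6474 peaks with a median width of 1126 bp and covered 9.34 Mb. The CAP-H list held 4369 peaks with a median width of 1380 bp and covered 8.08 Mb. Sequences not placed on a chromosome carried 998 SMC2 and 604 CAP-H peaks. Chromosome lengths were taken as the highest peak coordinate of either list, which overstates density where the end of a chromosome has no peak.

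**Figure D1:**
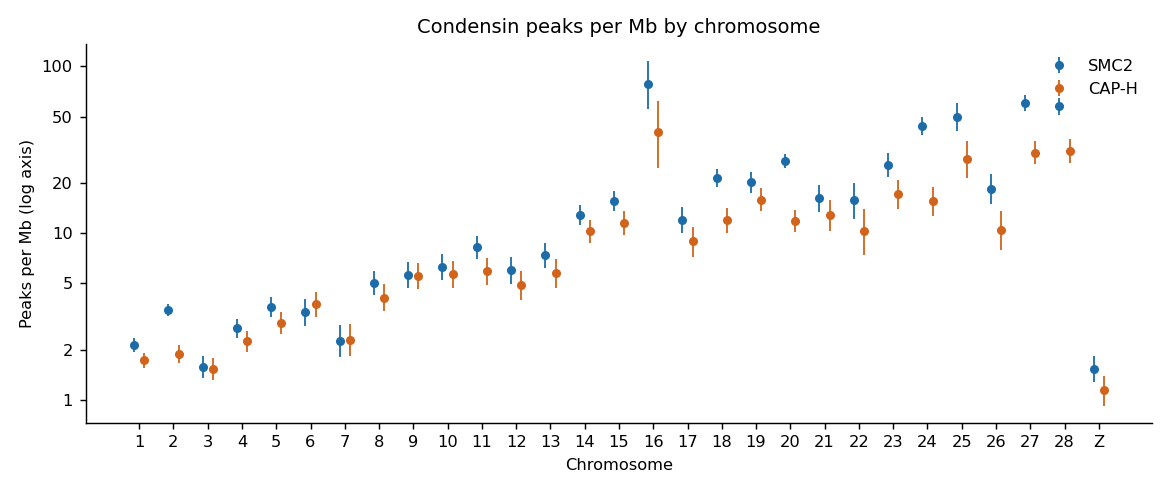
Peaks per Mb on each chromosome except W, on a log axis, for SMC2 (blue) and CAP-H (orange); bars are 95% exact Poisson intervals for counting error. Density rises from the large chromosomes on the left to 60.1 SMC2 peaks per Mb on chromosome 27 and 78.6 on chromosome 16, with Z lowest at 1.53.

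Several of the strongest SMC2 peaks lay near the first base or the highest listed coordinate of a chromosome. The highest score of the authors, 3100, was shared by 14 SMC2 peaks, of which 12 were on placed chromosomes and 2 on unplaced sequence. Of the 12 placed peaks, 3 lay within 50 kb of the first base and 6 within 50 kb of the highest listed coordinate of their chromosome (build galGal4). That coordinate is set by the peaks, and for 2 of the 6 by the peak itself or a peak overlapping it. Leaving such cases out, 7 of 12 remained, against 2.19% (1.82 to 2.61) of all placed SMC2 peaks, a count made after the data were seen. At the first bases these were chromosome 24 from 7 to 2820, chromosome 14 from 10036 to 11430 and chromosome 4 from 40150 to 43671. At the far side they were chromosome 8 from 28741902 to 28746871, chromosome 9 from 23435765 to 23440701 and chromosome 11 from 19377506 to 19381654. The others there were chromosome 12 from 19876899 to 19880761, chromosome 17 from 10394486 to 10401413 and chromosome 18 from 11199962 to 11206058. Away from the ends were chromosome 5 from 3065817 to 3106172, chromosome 22 from 2751119 to 2754072 and chromosome Z from 27165565 to 27173989. Each of the 14 peaks overlapped a CAP-H peak.

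Peaks wider than 30 kb were found at a single site in the CAP-H list and at a pair of sites in the SMC2 list. On chromosome 5 an SMC2 peak of 40.4 kb, from 3065817 to 3106172, enclosed a CAP-H peak of 30.3 kb, from 3074067 to 3104342. On chromosome Z an SMC2 peak of 31.3 kb, from 42623493 to 42654744 with a score of 2808, overlapped 5 CAP-H peaks, the widest of 13.3 kb from 42631217 to 42644526. The next widest SMC2 peaks, of 17.5 kb and 16.7 kb, were both on chromosome 20, at 10861505 to 10879048 and 10363050 to 10379778. Each had 1 CAP-H partner, of 18.1 kb and 17.1 kb. The CAP-H file gives no score, so its 10 widest peaks were named in place of its strongest, a choice made after the file was seen. Width need not follow strength. In the SMC2 list the widest peak had the highest score, 3100, but the 16.7-kb peak had 60.46, below the list median of 74.5. Of those 10, 3 overlapped no SMC2 peak: chromosome 1 from 100346308 to 100368074, chromosome 27 from 4611 to 23927 and chromosome 17 from 16418 to 33880.

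**Figure D2:**
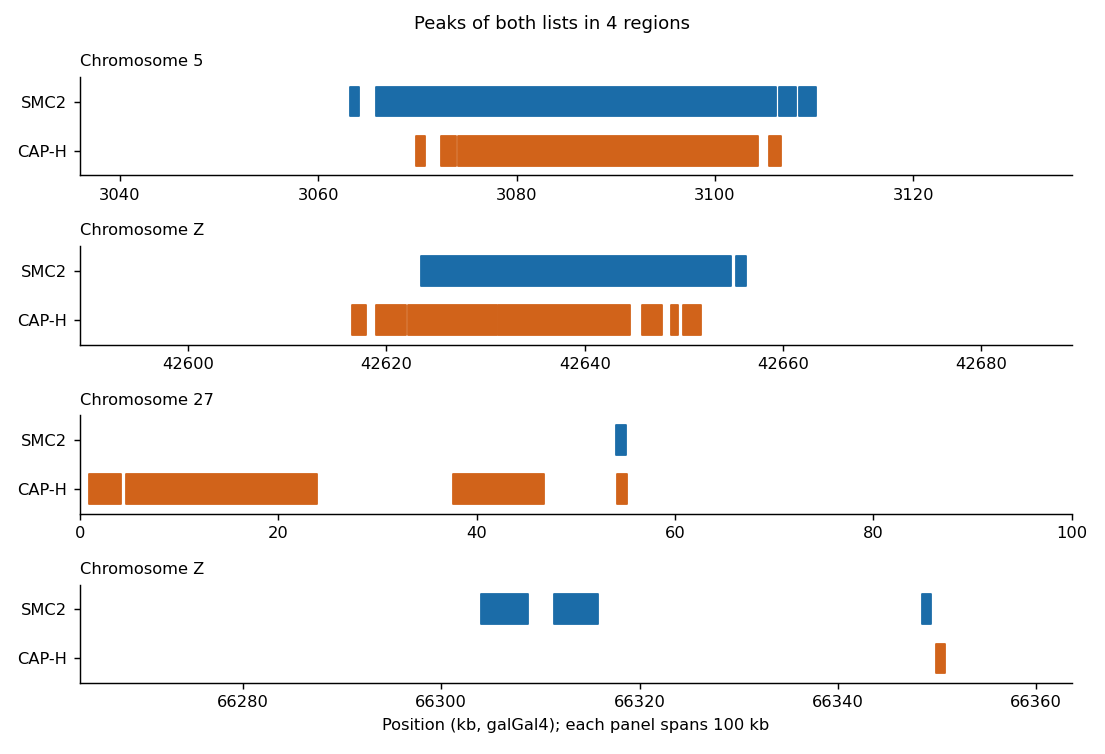
Peaks of both lists as boxes in 4 regions of 100 kb, with position in kb (galGal4) on the horizontal axis. From the top: the 40.4-kb SMC2 peak on chromosome 5, the 31.3-kb SMC2 peak on Z, the CAP-H peaks at the start of chromosome 27, and the SMC2 peaks on Z at 66303970 to 66315837 that had no CAP-H partner.

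The windows of 100 kb with most peaks of the full lists lay on microchromosomes 18, 20, 24 and 27. The SMC2 window with most peaks was on chromosome 24 from 5400001 to 5500000, with 22 SMC2 and 4 CAP-H peaks; the highest window of 1000 shuffles within chromosomes held 19. It was followed by chromosome 27 from 4300001 to 4400000 with 20 SMC2 peaks, and by chromosome 18 from 10100001 and chromosome 20 from 10300001 with 19 each. Windows on chromosome 18 from 10000001, chromosome 24 from 5600001 and chromosome 27 from 4000001 tied at 18. The CAP-H window with most peaks was on chromosome 18 from 10200001 to 10300000, with 15 CAP-H and 14 SMC2 peaks, against a highest window of 13 in the shuffles. The adjoining window from 10100001 had 14 CAP-H peaks. Windows on chromosome 24 from 5600001 and on chromosome 27 from 4000001 and 4300001 had 13 each, so 4 of the 5 richest CAP-H windows were also among the 7 SMC2 windows named. With the upper 50% of SMC2 peaks by score the richest window lay on macrochromosome 1, from 47900001 to 48000000, with 16 peaks against a highest shuffle of 15.

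The second comparison asked how far the SMC2 and CAP-H sites coincide. Of the 6474 SMC2 peaks, 2009 overlapped a CAP-H peak by at least 1 bp, or 31.0% (95% exact binomial interval 29.9 to 32.2). Of the 4369 CAP-H peaks, 1852 overlapped an SMC2 peak, or 42.4% (40.9 to 43.9). On microchromosomes 53.3% (51.1 to 55.6) of CAP-H peaks had an SMC2 partner, against 33.9% (30.0 to 37.9) on chromosomes 6 to 10, 31.0% (28.4 to 33.8) on macrochromosomes and 21.3% (13.5 to 30.9) on Z. Among single microchromosomes the CAP-H share ran from 34.5% on chromosome 26 and 37.6% on chromosome 17 to 67.7% on chromosome 27 and 95% on chromosome 16, which had 20 CAP-H peaks. Of SMC2 peaks, 35.5% (33.8 to 37.1) on microchromosomes, 37.0% (33.1 to 41.0) on chromosomes 6 to 10, 24.5% (22.3 to 26.7) on macrochromosomes and 13.5% (8.06 to 20.7) on Z had a CAP-H partner.

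When the CAP-H peaks were shuffled within chromosomes 1000 times, a mean of 6.02% of SMC2 peaks overlapped 1, with a range of 5.16% to 6.86%. The observed share was 5.15 times that mean. For CAP-H peaks against shuffled SMC2 peaks the mean was 8.66% (7.62% to 9.73%), and the observed share was 4.89 times as high. Chance overlap was more frequent where peaks were dense: the shuffle mean on microchromosomes was 5.56% for SMC2 and 8.69% for CAP-H, against 0.634% and 0.884% on macrochromosomes. The observed shares were thus 6.38 and 6.14 times the shuffle mean on microchromosomes and 38.6 and 35.1 times on macrochromosomes. On unplaced sequence they were only 1.33 and 1.28 times as high, at 25.9% against 19.5% for SMC2 and 40.4% against 31.7% for CAP-H. On placed chromosomes alone the ratios were 8.98 for SMC2 and 8.63 for CAP-H, and 4.57 and 4.58 when each peak was instead moved by 20 to 100 kb, a setting chosen after the data were seen. Under the stricter rule of an overlap of at least 50% of both peaks, 17.5% of SMC2 and 26.0% of CAP-H peaks were shared.

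Shared SMC2 sites were stronger than unshared ones. The median score was 108 (interquartile range 73.9 to 188) for the 2009 shared SMC2 peaks and 68.0 (57.1 to 87.8) for the 4465 others, a ratio of 1.59 (bootstrap 95% interval over peaks 1.53 to 1.67). In 5 equal groups by score, 13.8% (11.99 to 15.8) of the weakest SMC2 peaks and 67.6% (64.9 to 70.1) of the strongest overlapped a CAP-H peak. The shuffle mean for those groups was 3.51% and 11.03%. Among the 130 SMC2 peaks with a score of at least 500, 127 were shared. Shared CAP-H peaks were wider, with a median of 1858 bp against 1177 bp. In 5 equal groups by width, 21.4% (18.7 to 24.3) of the narrowest and 71.1% (67.9 to 74.0) of the widest CAP-H peaks had an SMC2 partner.

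**Figure D3:**
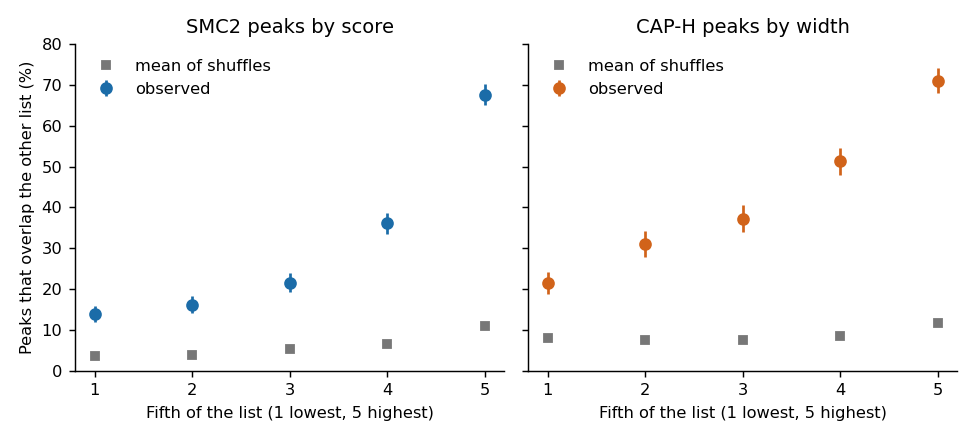
Share of SMC2 peaks (left, 5 equal groups by score) and of CAP-H peaks (right, 5 equal groups by width) that overlap the other list, in percent, with 95% exact binomial intervals; grey squares are the mean of 1000 shuffles. The share rises from 13.8% to 67.6% for SMC2 and from 21.4% to 71.1% for CAP-H.

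The balance of SMC2 and CAP-H peaks was uneven between chromosomes. Over all peaks there were 1.48 SMC2 peaks per CAP-H peak (95% exact interval 1.43 to 1.54). Chromosome 24 had 2.84 (2.24 to 3.61), chromosome 20 had 2.28 (1.90 to 2.74) and chromosome 2 had 1.84 (1.59 to 2.14). The other macrochromosomes together had 1.19 (1.09 to 1.30) and the other microchromosomes 1.51 (1.42 to 1.61). Some of these microchromosomes were above the value of chromosome 2: chromosome 27 at 1.98 (1.63 to 2.41), chromosome 16 at 1.95 (1.11 to 3.53) and chromosome 28 at 1.86 (1.52 to 2.29). Chromosome 18 had 1.80 (1.45 to 2.24). SMC2 peaks were also wider on chromosomes 2, 20 and 24, with a median of 1359 bp on chromosome 2, against 973 bp on the other macrochromosomes. On chromosomes 20 and 24 the medians were 1589 bp and 1523 bp, against 1096 bp on the other microchromosomes, of which chromosome 16 alone was higher at 1655 bp. CAP-H peaks were wider there too, at 1748.5 bp, 1940.0 bp and 1801 bp on chromosomes 2, 20 and 24, against 1319 bp on the other macrochromosomes and 1443.5 bp on the other microchromosomes. These 3 chromosomes were singled out after their values were seen.

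**Figure D4:**
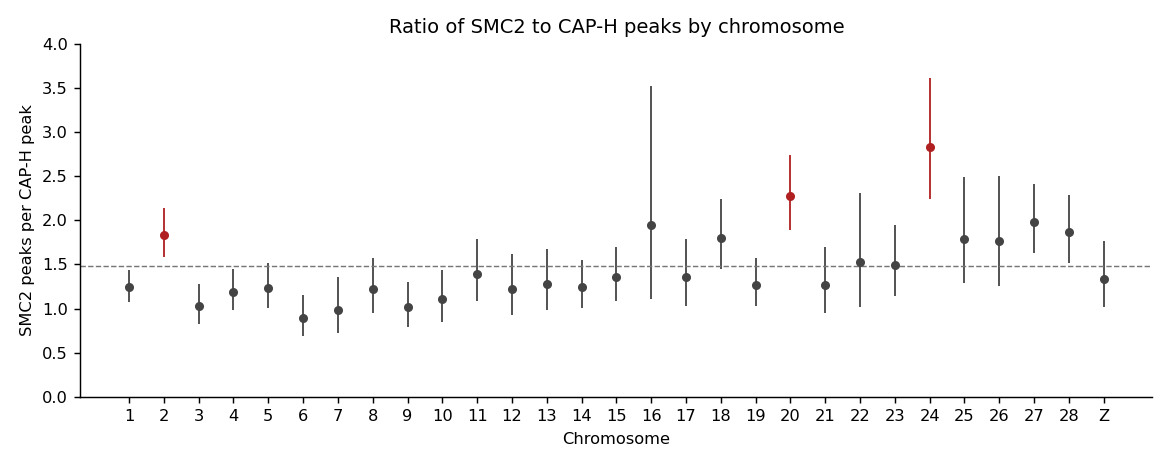
SMC2 peaks per CAP-H peak on each chromosome except W, with 95% exact intervals for counting error; the dashed line is the ratio over all peaks, 1.48, and chromosomes 2, 20 and 24 are in red. Chromosome 24 is highest at 2.84 and chromosome 20 next at 2.28.

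The last comparison asked how condensin signal is arranged around transcription start sites (TSSs), using the authors' aggregate profiles from 5000 bp upstream to 5000 bp downstream. In the Sample column, which is not set against Control, SMC2 signal peaked just downstream of the TSS. CAP-H signal in that column formed a broad plateau across it. In the SMC2 pull-down the mean signal within 100 bp of the TSS was 6479, or 1.46 times the mean of the outer flanks beyond 4000 bp (4452 ± 119, SD over 2000 bases). Its highest value, 7104, was 78 bp downstream, and its width at mid height was 537 bp over all bases. In the CAP-H pull-down the signal within 100 bp was 8469, or 1.27 times the outer flanks (6644 ± 148). Its single highest base, 9224 at 843 bp downstream, lay in a step of 49 bases, about 1 read length of 50 bp, that was also in the Control column. With a running median over 3 read lengths, a setting chosen after the data were seen, the highest CAP-H value was 8703 at 365 bp upstream, at position -365, and the width at mid height was 2960.0 bp. Its downstream edge, at 1410 bp, lay beside a rise near 1370 bp that was also in Control. With the upstream flank alone the width was 2565 bp. With the same running median the highest SMC2 value lay 40 bp downstream and the width was 759 bp.

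The Control column of both profiles fell at the TSS. Within 100 bp it was 0.764 times its outer flanks in the SMC2 file and 0.709 times in the CAP-H file. The Difference column, Sample minus Control, peaked 78 bp downstream in the SMC2 file at 3950.0 and 80 bp downstream in the CAP-H file at 4291. The contrast in summit position between the subunits was thus in Sample and not in Difference. The width of Difference at mid height was 659 bp for SMC2 and 1172 bp for CAP-H. With 1 library each, whether the subunits differ in shape at the TSS was not tested. The fall of Control made up 31.7% of the rise of Difference for SMC2 and 51.0% for CAP-H. The ratio of Sample to Control went from 1.11 in the outer flanks to 2.12 at the TSS for SMC2, and from 1.02 to 1.83 for CAP-H. In the 500 bp upstream and the 500 bp downstream of the TSS it was 1.74 and 1.85 for SMC2. For CAP-H it was 1.61 and 1.64 there. Between 500 and 2000 bp upstream the Sample signal was 1.11 times the outer flanks for SMC2 and 1.19 times for CAP-H. The number of TSSs behind the profiles and the scaling of the columns are not given in the sources used here, so the ratios and shares between columns hold only for Control as it stands in the files. With Control divided by the common divisor of its values, 2 for SMC2 and 3 for CAP-H, a setting chosen after the data were seen, its fall made up 18.9% and 25.8% of the rise.

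**Figure D5:**
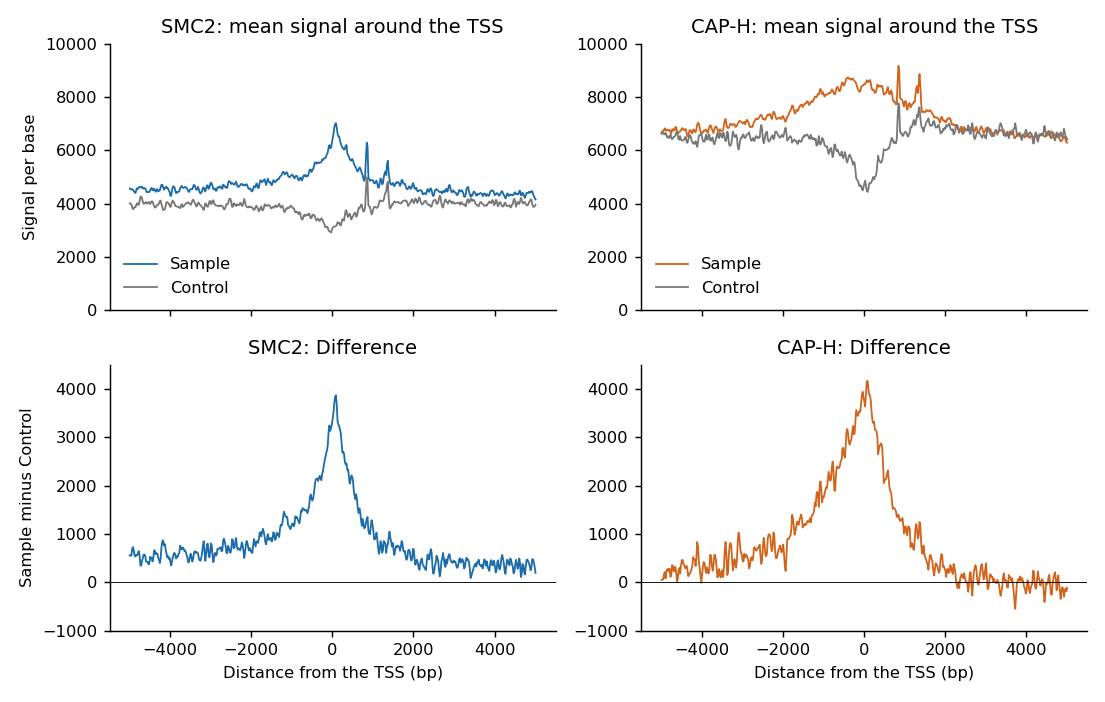
Mean signal per base (top) and Sample minus Control (bottom) against distance from the TSS in bp, in bins of 20 bp, for SMC2 (left) and CAP-H (right); Control is grey. SMC2 Sample rises to a summit 78 bp downstream, CAP-H Sample is broad, and Control falls at the TSS in both.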

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

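The tests of the SMC2 threshold, of weak peaks and of the Control signal below were chosen only after the results were seen, and the threshold test was changed from plain to relative ratios after the plain ones were seen; those of chromosome copies, dense clusters and peak edges were set before their results were known, but the reading of the copies test was made stricter afterwards.

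In the outer downstream flank of the TSS profiles, beyond 4000 bp, the mean Difference was 355 (SD over bases 117) in the SMC2 file and -49.4 (SD 165) in the CAP-H file. In the upstream flank it was above 0 in both, at 558 and 280. The sign depends on the scaling of Control, which is unknown, and the difference between the files was not tested, with 1 library each.

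SMC2 peaks were more numerous relative to CAP-H, and wider, on chromosomes 2, 20 and 24, with a ratio 1.60 times (1.42 to 1.79) that of the other chromosomes of their classes. The excess was not confined to a few dense clusters, since the relative ratio was 1.57 (1.33 to 1.85) without the richest 10% of 100-kb windows of every autosome. A looser SMC2 threshold was not excluded. At a score of 59.7, which equalled the lists on the other autosomes, the relative ratio was 1.48 (1.31 to 1.67). On chromosomes 2, 20 and 24 alone the relative ratio was 1.45 (1.20 to 1.74), 1.39 (1.13 to 1.70) and 1.71 (1.33 to 2.19). The plain ratio was 1.66 (1.37 to 2.02) on chromosome 20 and 2.04 (1.59 to 2.63) on chromosome 24. On chromosome 2 the plain ratio of 1.16 (0.989 to 1.37) did not exclude 1. SMC2 peaks on chromosomes 2, 20 and 24 were also less often shared, at 17.7%, 27.1% and 25.8%. The shares were 24.5% on all macrochromosomes and 35.5% on all microchromosomes, these 3 included. CAP-H peaks on chromosomes 2, 20 and 24 were shared at 32.9%, 59.4% and 67.0%. On all macrochromosomes and all microchromosomes the CAP-H shares were 31.0% and 53.3%. More SMC2 peaks per CAP-H peak leave fewer partners for each SMC2 peak, so the lower SMC2 share may follow from the ratio. The intervals of these ratios cover counting error only, and the chromosomes were picked for a high ratio, so these tests decide no cause. Extra copies of these chromosomes in the cells stay open: 12 of 15 equal segments had a ratio above that of their class, the number set beforehand, but only 9 by their whole interval, and the chromosomes were picked for a high ratio, so the count decides nothing. A gain present in both the SMC2 and the CAP-H cells could raise both lists and leave the ratio unchanged. A difference in binding between the subunits was not tested, and the inputs that would show copy number were not analysed here.

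Most peaks of each list lacked a partner in the other. Imprecise peak edges are argued against, because a tolerance of 500 bp raised the SMC2 share only 1.07 times. Weak peaks that missed the threshold of the other list are a candidate explanation: the strongest of 5 score groups was shared 4.89 times as often as the weakest. The shuffle mean rose too, from 3.51% to 11.03%, so the share over the shuffles rose from 3.94 to 6.13 times. SMC2 sites of condensin II, which lacks CAP-H, stay open as a biological explanation that was not tested. That explanation could bear only on unshared SMC2 peaks, and not on the 2517 CAP-H peaks without an SMC2 partner.

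Difference had a summit at the TSS in both files. For SMC2 the fall of Control could account for 31.7% of the rise from the outer flanks, and for 36.4% of that from 300 to 500 bp away to within 100 bp, but not for the rest, which was in the Sample column. For CAP-H it made up 51.0% of the rise from the outer flanks and 103% of that from 300 to 500 bp away, so the sharp summit may come from Control alone. The broader CAP-H elevation was in the Sample column itself, which a fall of Control does not alter. Its median between 500 and 2000 bp lay 7.79 SD of the flank bases above the flanks, but bases are not independent. Control was also above its flanks downstream, at 6943 from 1000 to 1500 bp and 6922 from 1500 to 2000 bp, against 6529. Part of the downstream elevation was thus in both columns. With Control divided by the common divisor of its values, its part of the rise from 300 to 500 bp away was 22.3% for SMC2 and 111% for CAP-H. Its part of the rise from the outer flanks was then 18.9% and 25.8%. Why Control fell at the TSS was not tested.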

How the results depend on the processing

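Leaving out chromosomes 2, 20 and 24, moving peaks by 20 to 100 kb, running medians, 1-sided flanks and a divided Control were chosen after seeing the data; the other alternatives were planned. Of 58 alternative values for 17 results, 34 stayed within their interval, spread or, for counts, 1.5-fold range, 23 did not, and 1 changed sign; no share fell to its shuffle mean. With overlap of at least 50% of both peaks, 17.5% of SMC2 and 26.0% of CAP-H peaks were shared (6.93 and 6.95 times the shuffles), and the score ratio of shared to unshared peaks was 1.79. By width in place of score, with direct overlap, that ratio was 1.42. With edges within 500 bp the shares were 33.2% and 45.4%. With the upper 50% of SMC2 peaks by score they were 46.1% and 32.7%, and with the SMC2 list reduced to the length of the CAP-H list 39.2% and 36.9%. Fewer SMC2 peaks leave fewer partners for CAP-H, and the SMC2 peaks left out by score were seldom shared (13.8% in the weakest of 5 groups). Without chromosomes 2, 20 and 24 the SMC2 share was 32.9%. On placed chromosomes the folds over shuffles were 8.98 and 8.63, since shuffles within short unplaced sequences often meet a peak, but 4.57 and 4.58 with peaks moved nearby. Density on microchromosomes over macrochromosomes was 9.71 for the upper 50% of SMC2 peaks, and 6.48 (SMC2) and 5.32 (CAP-H) with peaks within 1 kb merged; the cause was not tested. Windows of 1 Mb held up to 116 SMC2 and 76 CAP-H peaks, being larger. With the running median, which removes a step of 1 read length, the highest Sample base went from 843 to -365 bp (CAP-H) and from 78 to 40 bp (SMC2). With Control divided by the common divisor of its values, its fall made up 18.9% (SMC2) and 25.8% (CAP-H) of the rise of Difference. Score alternatives for CAP-H and all per-gene, gene-list and TSS-distance alternatives were not run, for lack of scores and of an annotation of the same build. Unknown depth limits what a missing peak can show.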

Other observations

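Everything in this part was chosen only after the results were seen, and the tests of the centromere and of the SMC2 link replaced earlier counts whose values were known.

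SMC2 peaks formed long chains, counted as at least 5 peaks less than 10 kb apart on a placed chromosome, and there were 126. No number of chains from shuffles is given, so how many random placement would yield where peaks are dense is not known. The chain with most covered sequence lay on chromosome 20 from 10813006 to 10951846, where 24 SMC2 peaks covered 60.0% of 139 kb and 8 CAP-H peaks covered 28.7%. On chromosome 24 from 5584200 to 5670458, 18 SMC2 peaks covered 75.3% and 13 CAP-H peaks 59.8%. Macrochromosomes held 3 of the 6 chains with the highest median score, and the chains ranked 7 and 8 lay on microchromosomes 28 and 25. On chromosome 1 from 47923755 to 47961942 and from 47972873 to 48035726, 8 and 14 SMC2 peaks had median scores of 546 and 269, against a median of 93.1 over the 126 chains. All 8 and all 14 overlapped CAP-H peaks. On chromosome 3 from 104117776 to 104141325, 5 SMC2 peaks had a median score of 518, and 3 of the 5 overlapped CAP-H peaks. The chain with the highest median score, 925, lay at the start of chromosome 15, from 820 to 25790. A pair on chromosome 16, from 137119 to 174774 and 204466 to 230220, had 839 and 371.

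Peaks were frequent at the start of chromosomes. In the first 20 kb of the 30 placed chromosomes lay 35 SMC2 and 28 CAP-H peaks, against shuffle means of 10.7 and 6.29 and highest shuffles of 21 and 17. Of 43 placed SMC2 peaks with a score over 1000, 9 lay within 50 kb of the first base, or 20.9% (10.04 to 36.0), against 1.04% (0.789 to 1.35) of all placed SMC2 peaks. Some stretches near the start held CAP-H peaks alone. On chromosome 27, CAP-H peaks at 931 to 4173, 4611 to 23927 and 37555 to 46788 had no SMC2 partner, nor had those on chromosome 17 at 16418 to 33880, 34433 to 43453 and 48350 to 54777.

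A hypothesis for the widest peaks is that they mark centromeres without tandem repeats, which chickens are known to have on chromosomes 5, 27 and Z. The sites on 5 and Z prompted the idea and cannot test it. Of the 3 other sites among the 3 widest peaks of each list, 1 lay on those chromosomes, on 27, and the others on 20 and 1. No centromere position of this build was used here, so a centromere and another wide site cannot be told apart.

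Among the 28 SMC2 peaks with a score of at least 1653, 26 had a CAP-H partner. The 2 without lay side by side on chromosome Z, at 66303970 to 66308706 (score 1653) and 66311344 to 66315837 (score 2131). A hypothesis is a link to the SMC2 gene, which is also on Z, or to the constructs that replaced it in these cells. Of the 26 partnered peaks of that strength, 3 also lay on Z, or 11.5%, and the 2 adjacent peaks count as 1 site, so a shared chromosome decides nothing. On chromosome 22, which carries NCAPH, the widest of 19 CAP-H peaks without an SMC2 partner was 3173 bp. It ranked 113 by width among the 2517 such CAP-H peaks, which have no score. The position of the SMC2 gene in this build was not used here.

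The profiles of both files had a step from about 829 to 878 bp downstream of the TSS, in Sample and Control alike, of 48 or 49 bases. Its height over its surroundings was 25.5% in the SMC2 Sample and 26.9% in its Control, and 14.98% and 17.3% in the CAP-H file.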
